A study of Homo sapiens with 9 samples.

How the data were processed

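RNA was sequenced from Caco-2, a human colon adenocarcinoma cell line kept in medium with lipid-depleted serum. All 9 libraries came from cells given 10 µM lovastatin for 48 h. The 3 groups of 3 libraries had lovastatin alone, lovastatin with 10 µM SGA360, or lovastatin with 10 µM SGA315. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from poly(A)-enriched RNA with an Illumina kit. Group and replicate number were taken from the labels. The labels do not say that the 3 libraries of a group came from separate cultures.

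The deposited table holds raw read counts, whole numbers per RefSeq transcript accession and library, not normalised, per the file headers and the values. TopHat2 2.0.13, HTSeq 0.5.4p3 and the genome build hg19 are named in the submitters' processing notes, without the role of each. The annotation release, the strand setting and any filter are not given in the sources used here. Because strand was not stated, reads of overlapping and antisense genes may not have been separated. The table has 65325 transcript entries. Gene names came from a RefSeq gene table of assembly GRCh38.p14 (64340 entries matched) and from GENCODE 29 (571 matched). 414 entries matched neither, held 0.22% of all counts, and stayed out of library sizes and tests. Because the reference assembly differs from the authors' build, no coordinates are given, and the RefSeq table of GRCh38.p14 was used only for names and for which genes overlap.

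Transcripts of a gene repeat the reads of their shared exons: in genes with 2 or more entries and at least 1000 counts, the median count of the second highest entry was 99.8% of the highest. The sum over all entries was 3.11 times the sum over 1 entry per gene. The entry with the highest total over all 9 libraries therefore stood for each gene. Of 23 sets of genes with identical counts, 1 gene each was kept (43 dropped), which left 27693 genes. Depth over 1 entry per gene was 12343137 to 16882576 counts per library (38223419 to 52396539 over all entries). 3 counts, the limit that a count of 0 allows, correspond to 0.178 to 0.243 CPM, the deposited counts scaled to a common library size. Intervals of counts and such floors cover counting error only. A fold against a floor takes the counts of the other group as exact. No column of sample values was left unused.

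Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM scaling, filterByExpr (minimum count 10, minimum total 15), 1 coefficient per group and no covariate. All 9 libraries entered 1 fit. The filter left 14683 genes. The 3 comparisons were each ligand against lovastatin alone and SGA360 against SGA315. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene is called at an adjusted p under 0.05. Every adjusted p of a gene is from this test unless another is named. Levels are mean CPM ± SD over 3 libraries, changes are log2 fold changes with SE, and intervals of a difference are 95% intervals from the same fit.

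Before the data were examined, 26 gene lists, the comparisons, the alternatives and the rule for named genes were written down. The rule took, per comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups' CPM, 14 genes fixed by name, and up to 3 tested members of each list with the smallest p. 29 genes outside the rule, and also SPRY1, are named in the closing section and were chosen after their values were seen. A few members of lists beyond those 3 are given as examples of their list and were likewise picked after their values were seen. Lists were tested with camera in limma 3.58.1 on voom log2 counts with a preset inter-gene correlation of 0.01, adjusted over 72 tests (24 lists with at least 3 tested members, 3 comparisons). Counts of called members are given over all genes and adjusted over the list alone. Some genes that the rule takes, and 1 of the tested lists, are not reported here.

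The test was checked on simulated counts for 14683 genes, with 200 genes changed. At 2-fold it recovered 94%, 96% and 94% of the changed genes for SGA360, SGA315 and their difference, and at 1.25-fold 67%, 66% and 55%. False calls made up 5.3%, 3.6% and 6.3% of calls. Far fewer genes were changed in these simulations than were called in the data, and libraries were drawn independently. The rates therefore need not hold for the data. To judge the overlap of the responses, groups without change were simulated 20 times against the 3 shared lovastatin libraries.

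Alternatives fixed in advance were RLE scaling, DESeq2 1.42.0, no filter on low counts, a fit of the compared groups only, a replicate block, leaving out each library, and, for the lists, camera with an estimated correlation and fry. Added after the data were seen were a test against a 1.5-fold change (glmTreat), scaling to totals only, the lowest accession of each gene, all transcript entries, and a fit without ribosomal RNA genes. The rule that names a correlation as moved, by more than the SD of its leave-one-out values, was also set after the values were seen. Within each group the counts of every pair of libraries differed by more than counting noise (chi-square per degree of freedom 1.36 to 2.4), so all were kept as separate libraries. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.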

Results

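Gene expression was measured by poly(A) RNA sequencing in Caco-2, a human colon adenocarcinoma cell line used as a model of the intestinal epithelium. All 9 libraries came from cells given 10 µM lovastatin, a cholesterol-lowering statin, for 48 h. 3 libraries had lovastatin alone, 3 had lovastatin with 10 µM SGA360 and 3 had lovastatin with 10 µM SGA315. Both compounds are described in the labels as selective ligands of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, and their doses and times were matched. Cells without lovastatin were not analysed here, so each comparison is between lovastatin-treated cells. Depth over 1 transcript per gene was 14141236 to 16316266 counts per library with lovastatin alone, 12343137 to 16882576 with SGA360 and 12894186 to 14747300 with SGA315. The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. That spread was small, with a biological coefficient of variation of 2.16%. Every library correlated best with a library of its own group, and the first principal component held 60.6% of the variance. Nuclear ribosomal RNA took 0.52 to 0.72% of counts with lovastatin alone, 0.43 to 0.66% with SGA360 and 0.24 to 0.32% with SGA315. Mitochondrial ribosomal RNA took 0.95 to 1.0%, 1.22 to 1.31% and 1.14 to 1.29%. Changes below are relative to TMM scaling: with scaling to totals only, the median log2 fold change of all genes moved from 0.02 to 0.14 for SGA360 and from 0.04 to 0.16 for SGA315.

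The comparison of SGA360 with lovastatin alone asked how this AHR ligand changed expression in lovastatin-treated cells. CYP1A1, which encodes a xenobiotic-metabolising cytochrome P450 and is a classical AHR target, fell 8.16-fold, from 44.6 ± 3.82 to 5.45 ± 0.402 CPM (mean ± SD, n = 3 each). Metallothionein genes, which encode small zinc-binding proteins, rose together: MT2A went from 1.17 ± 0.45 to 36.1 ± 4.23 CPM, 29.8-fold higher, and MT1X from 1.22 ± 0.475 to 21.4 ± 0.12 CPM, 17.5-fold higher. Genes of cholesterol synthesis and of DNA replication fell together. HMGCS1, which makes HMG-CoA, went from 498 ± 3.03 to 337 ± 5.43 CPM, and RRM2, a subunit of ribonucleotide reductase, from 226 ± 1.79 to 66.9 ± 3.77 CPM.

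Of the 8 tested genes of the AHR battery, 0 were higher and 7 lower with SGA360, and the counts were the same adjusted over the list alone. The median log2 fold change was −0.98 (camera, Benjamini-Hochberg adjusted p = 3.93e-05; adjusted p = 0.0444 with an estimated correlation). CYP1B1, another AHR-regulated cytochrome P450, fell by 1.06 ± 0.209 on the log2 scale (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.13e-05). The aldehyde dehydrogenase gene ALDH3A1 fell by 1.69 ± 0.151, the quinone reductase gene NQO1 by 0.89 ± 0.026 and the efflux transporter gene ABCG2 by 0.90 ± 0.071. The glucuronidation gene UGT1A6 fell by 1.17 ± 0.032, a value that is uncertain because the UGT1A genes share exons. TIPARP, an AHR-induced ADP-ribosyltransferase, had a log2 fold change of −0.03 ± 0.055 (adjusted p = 0.704), which was 0.09 with scaling to totals only. The AHR repressor gene AHRR fell by 0.23 ± 0.102 (adjusted p = 0.0436), a call that ended without lovastatin replicate 3 (adjusted p = 0.189), without SGA360 replicate 3 (adjusted p = 0.228), with DESeq2 (adjusted p = 0.112) and with scaling to totals only (adjusted p = 0.314). Over all 17 alternatives the adjusted p of AHRR was 0.00943 to 0.314. AHR itself fell by 0.18 ± 0.041 (adjusted p = 9.67e-05), to 69.8 ± 2.52 from 79.0 ± 2.45 CPM, and this call ended with scaling to totals only (−0.07, adjusted p = 0.144; 1.65e-05 to 0.144 over the alternatives).

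**Figure D1:**
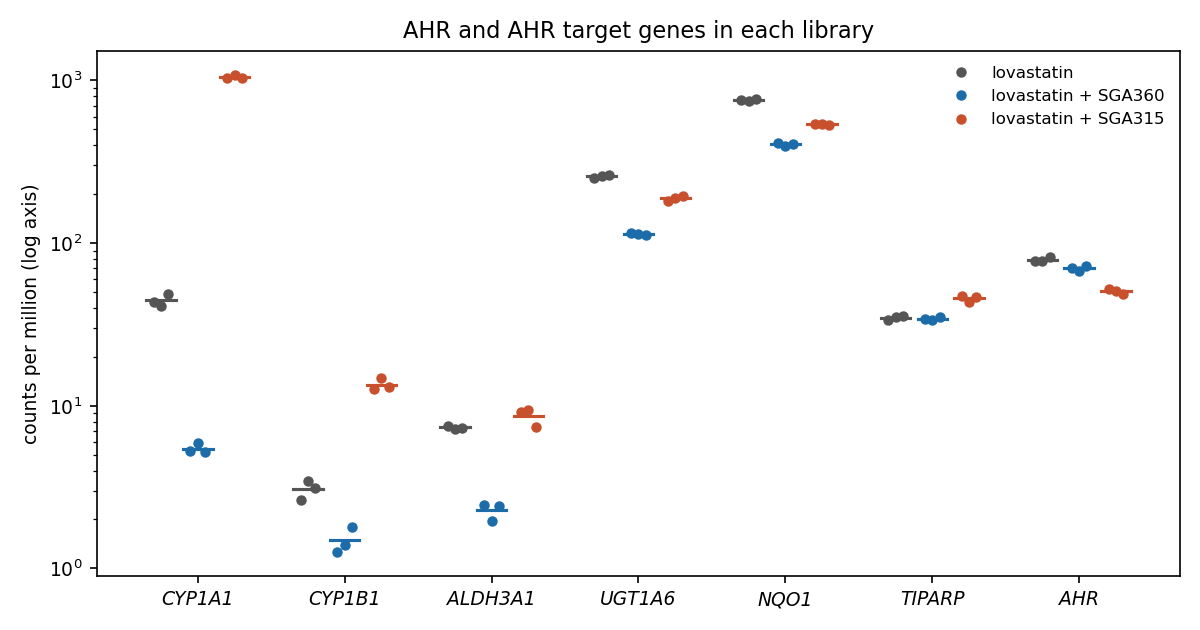
CPM on a log axis of AHR and 6 of its target genes in each of the 9 libraries (points) with the mean of each group (short lines), for lovastatin alone, lovastatin with SGA360 and lovastatin with SGA315. CYP1A1 had a mean of 44.6 CPM with lovastatin alone, 5.45 with SGA360 and 1053 with SGA315.

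Of the 20 genes of cholesterol synthesis, 17 were lower and 1 higher (2 higher with scaling to totals only), with the same counts adjusted over the list alone, at a median of −0.58 (camera adjusted p = 4.02e-13; adjusted p = 0.00739 with an estimated correlation). SQLE, the squalene epoxidase gene, fell by 0.38 ± 0.03, IDI1 by 0.84 ± 0.03 and DHCR7 by 0.74 ± 0.028. PMVK, which phosphorylates mevalonate 5-phosphate, rose by 0.29 ± 0.077. Of the 12 genes of cholesterol uptake and SREBP control, 3 were higher and 5 lower, over all genes and adjusted over the list alone, and camera made no call (adjusted p = 0.0942). The median was −0.05, and 0.06 with scaling to totals only, where 5 were higher and 5 lower. INSIG1, which retains SREBP in the endoplasmic reticulum, fell by 0.86 ± 0.032, and SREBF2, encoding the transcription factor of the sterol pathway, rose by 0.34 ± 0.029. NPC1L1, the intestinal cholesterol absorption transporter, had a log2 fold change of 0.05 ± 0.045 (adjusted p = 0.294), which was called with scaling to totals only (0.17, adjusted p = 0.000833) and which was −0.02 without lovastatin replicate 3 and −0.01 without SGA360 replicate 1. Its adjusted p over the alternatives was 0.000833 to 0.871. ABCA1, a cholesterol efflux transporter and target of the oxysterol receptor LXR, rose by 0.69 ± 0.072. Among 12 genes of fatty acid synthesis 8 were lower and 2 higher (camera adjusted p = 0.0171; adjusted p = 0.214 with an estimated correlation). They were 6 and 4 with scaling to totals only, where the median of −0.21 was −0.1. ACLY fell by 0.75 ± 0.027 and FASN by 0.72 ± 0.027, while GPAM rose by 0.79 ± 0.032. Of 11 genes of PPAR alpha and fatty acid oxidation 7 were lower and 1 higher (camera adjusted p = 0.0194; adjusted p = 0.176 with an estimated correlation). They were 6 and 2 with scaling to totals only, where the median of −0.2 was −0.09. CPT1A, which imports fatty acids into mitochondria, fell by 0.72 ± 0.08.

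**Figure D2:**
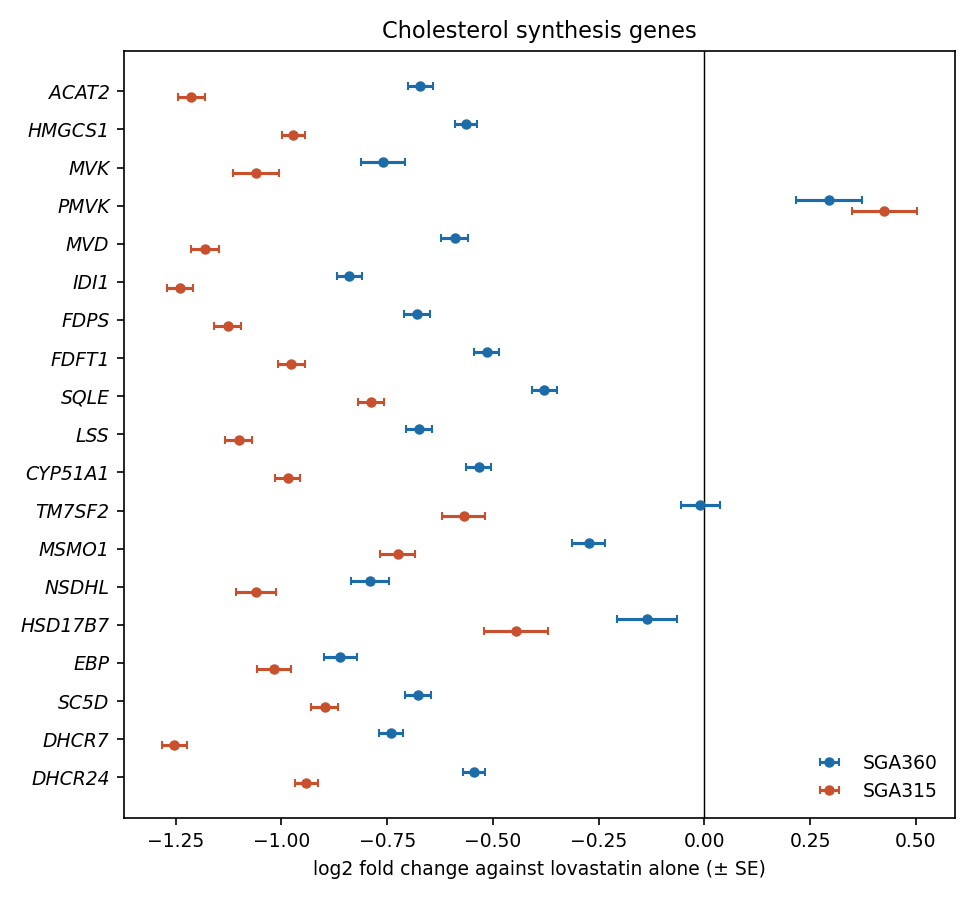
Log2 fold change against lovastatin alone (± SE, 3 libraries per group) of 19 cholesterol synthesis genes with SGA360 and with SGA315. By the direct test 18 of the 19 drawn were higher with SGA360 than with SGA315, and the other, PMVK, lay above 0 with both ligands.

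All 14 tested S phase genes and all 12 tested G2 and M phase genes fell with SGA360, over all genes and adjusted over each list alone. The medians were −0.89 (camera adjusted p = 9.3e-15; adjusted p = 0.0347 with an estimated correlation) and −0.51 (camera adjusted p = 7.5e-10; adjusted p = 0.0347 with an estimated correlation). PCNA, the replication clamp, fell by 1.09 ± 0.031, and the proliferation marker MKI67 by 1.08 ± 0.032. Of 7 crypt and stem cell markers 6 were lower (camera adjusted p = 0.000594; adjusted p = 0.162 with an estimated correlation), among them LGR5, a stem cell receptor and Wnt target, which fell by 1.67 ± 0.06. FOSL1, a subunit of the AP-1 transcription factor, fell 3.95-fold, the collagenase gene MMP1 3.99-fold, and the butyrophilin genes BTN1A1 and BTNL8 4-fold and 3.32-fold. WTAPP1 also fell, 3.2-fold, but it overlaps MMP1 in the RefSeq annotation of GRCh38.p14 and its value is uncertain. Among called genes of at least 5 CPM without overlap between the groups, the largest rises beside the metallothioneins were in DUSP15, a dual-specificity phosphatase gene (7.26-fold), NIBAN1 (6.17-fold), KLHDC7B (5.62-fold), PCLO (5.1-fold) and the Ras exchange factor gene RASGRP1 (4.72-fold).

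All 5 tested metallothioneins rose, over all genes and adjusted over the list alone, with a median of 4.72 (camera adjusted p = 2.45e-05; adjusted p = 0.0359 with an estimated correlation). The family shares sequence, so counts of its members are uncertain, and MT1G rests on 1 count with lovastatin alone; without it the median was 4.46. MT1H had 0 counts with lovastatin alone and 45 with SGA360. With scaling to totals only this was 15.2-fold higher against a floor of 3 counts over the group. The 45 counts were taken as exact, so this is not a lower limit. With TMM the value would be somewhat lower. Of 16 genes of the NRF2 response, which counters oxidants, 13 were lower and 3 higher (camera adjusted p = 0.000113; adjusted p = 0.0359 with an estimated correlation), led by PRDX1, a peroxidase gene that fell by 1.17 ± 0.027. Of 17 genes of the ATF4 and amino acid response 10 were higher and 5 lower (12 and 2 with scaling to totals only; camera adjusted p = 0.00958; adjusted p = 0.219 with an estimated correlation), with TRIB3 up by 0.72 ± 0.028; DDIT3 rose by 0.91 ± 0.043 but overlaps the more abundant MARS1. Of 15 endoplasmic reticulum chaperone genes 11 were lower and 4 higher (camera adjusted p = 0.028; adjusted p = 0.12 with an estimated correlation). These were 6 and 4 with scaling to totals only, where the median of −0.16 was −0.05. Of 15 genes of hypoxia and glycolysis 9 were lower and 4 higher (camera adjusted p = 0.00378; adjusted p = 0.157 with an estimated correlation), or 7 and 4 with scaling to totals only, where the median of −0.21 was −0.1. The glucose transporter gene SLC2A1 fell by 1.24 ± 0.031 and LDHA by 1.08 ± 0.027. For these lists the counts adjusted over the list alone were the same.

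Camera made no call with SGA360 for the other lists. Higher and lower members over all genes were 3 and 7 of 12 for the enterocyte brush border (5 and 7 adjusted over the list alone, 5 and 6 with scaling to totals only; camera adjusted p = 0.218), 3 and 6 of 10 for lipoproteins and lipid absorption (adjusted p = 0.122), and 3 and 3 of 8 for PXR and drug metabolism (adjusted p = 0.604). They were 5 and 1 of 9 for inflammation (adjusted p = 0.142) and 2 and 1 of 5 for LXR targets (adjusted p = 0.946). YAP targets had 2 and 2 of 8 (adjusted p = 0.417) and p53 targets 2 and 2 of 7 (adjusted p = 0.76), which were 4 and 0, and 4 and 2, with scaling to totals only. Of 3 tested goblet cell markers 0 were higher and 2 lower (camera adjusted p = 0.559): SPDEF fell by 0.83 ± 0.192 and AGR2 by 0.13 ± 0.036, the latter not called with scaling to totals only (−0.02, adjusted p = 0.7; 7.89e-05 to 0.7 over the alternatives). CHGB, the only enteroendocrine marker tested, rose by 0.28 ± 0.094 (adjusted p = 0.00736), a call that ended without lovastatin replicate 1 (adjusted p = 0.0524) and with DESeq2 (adjusted p = 0.0516; 0.000193 to 0.0524 over the alternatives). Of 3 mesenchymal markers VIM rose by 0.41 ± 0.031 while FN1 and COL1A1 fell (camera adjusted p = 0.201), and of 3 bile acid genes edgeR called 0 (camera adjusted p = 0.902), with unadjusted p = 0.213 for SLC51A, 0.291 for SLC51B and 0.856 for FGF19. Counts adjusted over the list alone were the same for all of these lists but the brush border. No member of the list of 9 mitochondrially encoded genes was found among the named entries, so that list was not analysed here.

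**Figure D3:**
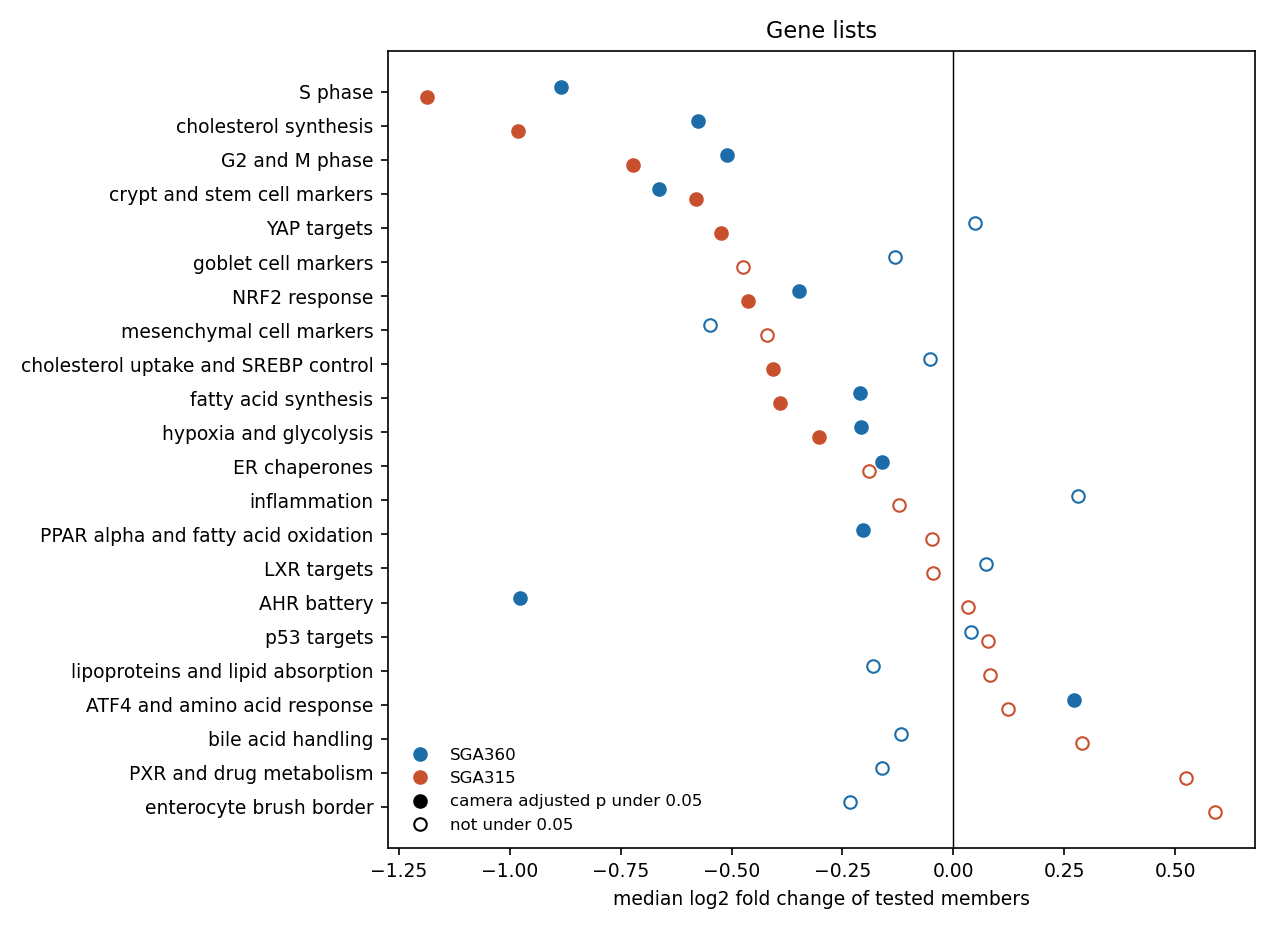
Median log2 fold change of the tested members of 22 gene lists with SGA360 and with SGA315 against lovastatin alone; filled points have a camera adjusted p under 0.05 with the preset correlation, and the metallothioneins (4.72 and 2.46) are not drawn. With scaling to totals only, the medians of cholesterol uptake (0.06) with SGA360, and of LXR targets (0.07) and PPAR alpha (0.07) with SGA315, changed side, and that of inflammation with SGA315 was 0.

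Of 14683 genes tested, 4605 were higher and 4604 lower with SGA360. The median size of the change among called genes was 0.35 on the log2 scale, and 460 rose and 209 fell at least 2-fold. The CPM of the groups did not overlap for 66.3% of genes, where chance gives 10%. With scaling to totals only the calls were 6477 higher and 3136 lower (67.4% higher, against 50% with TMM), and 429 and 407 genes passed a test against a 1.5-fold change.

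The comparison of SGA315 with lovastatin alone asked the same question of the other ligand. CYP1A1 rose 23.5-fold, from 44.6 ± 3.82 to 1053 ± 29.9 CPM, and CYP1B1 rose 4.41-fold, from 3.06 ± 0.416 to 13.5 ± 1.07 CPM (n = 3 each). Genes of cholesterol synthesis and of the cell cycle fell together, with HMGCS1 at 254 ± 4.47 CPM against 498 ± 3.03 and RRM2 at 58.3 ± 1.01 CPM against 226 ± 1.79. ID1, an inhibitor of differentiation induced by BMP signals, fell 4.31-fold, from 61.1 ± 1.09 to 14.2 ± 1.98 CPM. All 5 tested metallothioneins rose (camera adjusted p = 0.0171; adjusted p = 0.157 with an estimated correlation), with MT2A at 8.07 ± 1.26 CPM, 6.77-fold higher.

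The AHR battery had 3 members higher and 3 lower of 8 with SGA315 over all genes, and 4 higher and 3 lower adjusted over the list alone (median 0.03, camera adjusted p = 0.718); with scaling to totals only 4 were higher and 3 lower over all genes, at a median of 0.15. TIPARP rose by 0.39 ± 0.053 (adjusted p = 1.7e-09), while NQO1 fell by 0.49 ± 0.026, UGT1A6 by 0.45 ± 0.03 and ABCG2 by 0.42 ± 0.068. ALDH3A1 had a log2 fold change of 0.24 ± 0.113 (adjusted p = 0.0515) and AHRR of −0.18 ± 0.104 (adjusted p = 0.121). AHR fell by 0.65 ± 0.044, to 50.5 ± 1.8 CPM. Of 8 genes of PXR and drug metabolism 4 were higher and 2 lower, and 5 and 2 adjusted over the list alone (camera adjusted p = 0.435). GSTA1 and GSTA2 rose by 0.89 ± 0.074 and 0.82 ± 0.042 but are near-identical copies whose counts are uncertain.

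Of the 20 cholesterol synthesis genes 19 were lower and 1, PMVK, was higher with SGA315, also adjusted over the list alone, at a median of −0.98 (camera adjusted p = 5.93e-16; adjusted p = 0.00597 with an estimated correlation). SQLE fell by 0.79 ± 0.031 and IDI1 by 1.24 ± 0.031; ACAT2 fell by 1.21 ± 0.032 but overlaps SOD2 and the more abundant TCP1. Of the 12 uptake and SREBP control genes 9 were lower and 3 higher, also adjusted over the list alone (median −0.41, camera adjusted p = 0.00166; adjusted p = 0.0978 with an estimated correlation). INSIG1 fell by 1.40 ± 0.034, while SREBF2 rose by 0.16 ± 0.029. NPC1L1 fell by 0.14 ± 0.047 (adjusted p = 0.00518), from 69.6 ± 4.81 to 62.8 ± 2.01 CPM; the call ended without lovastatin replicate 2 (adjusted p = 0.0552) and with scaling to totals only (−0.02, adjusted p = 0.684; 0.000162 to 0.684 over the alternatives). ABCA1 rose by 0.72 ± 0.073, and among 5 LXR targets 2 were higher and 1 lower (camera adjusted p = 0.971), with a median of −0.05 that was 0.07 with scaling to totals only and a mean of 0.01. Of the 12 fatty acid synthesis genes 11 were lower and 1 higher (camera adjusted p = 2.45e-05; adjusted p = 0.0566 with an estimated correlation), with FASN down by 1.11 ± 0.027 and SCD, the stearoyl-CoA desaturase gene, down by 1.02 ± 0.027.

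All 14 S phase and all 12 G2 and M phase genes fell with SGA315 too, over all genes and adjusted over each list alone, at medians of −1.19 (camera adjusted p = 7.75e-14; adjusted p = 0.0347 with an estimated correlation) and −0.72 (camera adjusted p = 1.74e-08; adjusted p = 0.0368 with an estimated correlation). PCNA fell by 1.44 ± 0.032, and UHRF1, which maintains DNA methylation at replication, fell 3.72-fold. Of 7 crypt and stem cell markers 6 were lower (camera adjusted p = 0.00399; adjusted p = 0.219 with an estimated correlation), with LGR5 down by 1.47 ± 0.06 and AXIN2, a Wnt feedback gene, down by 0.92 ± 0.046. Of 8 YAP targets 6 were lower and 1 higher (6 and 0 with RLE; camera adjusted p = 0.0191; adjusted p = 0.157 with an estimated correlation), with ANKRD1 down by 0.90 ± 0.049 and CCN1 down by 0.80 ± 0.059. The immediate early gene EGR1 fell 3.91-fold, FOSL1 4.26-fold, BTN1A1 5.02-fold and the endothelin gene EDN1 3.48-fold. MYBPH fell 5.28-fold and MST1 rose 4.35-fold, but both overlap a more abundant gene (CHI3L1 and APEH) and are uncertain. Further large rises were in KLHDC7B (6.75-fold), NIBAN1 (4.72-fold), the non-coding RNA gene LINC00886 (4.43-fold), PCLO (4.27-fold) and N4BP2L1 (4.25-fold).

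All 5 tested metallothioneins rose with SGA315, also adjusted over the list alone (median 2.46, or 2.37 without MT1G; camera adjusted p = 0.0171; adjusted p = 0.157 with an estimated correlation). MT1H had 6 counts against 0. With scaling to totals only this was 2.2-fold higher against a floor of 3 counts over the group. The 6 counts were taken as exact, so this is not a lower limit. With TMM the value would be somewhat lower. Of 16 NRF2 response genes 13 were lower and 3 higher (camera adjusted p = 0.000496; adjusted p = 0.0419 with an estimated correlation), with PRDX1 down by 1.15 ± 0.027 and the thioredoxin reductase gene TXNRD1 down by 0.51 ± 0.027. Of 15 hypoxia and glycolysis genes 8 were lower and 3 higher (camera adjusted p = 0.00327; adjusted p = 0.157 with an estimated correlation), or 8 and 5 with scaling to totals only, where the median of −0.3 was −0.18. SLC2A1 fell by 1.75 ± 0.033. The other lists had no camera call. Among 12 brush border genes 7 were higher and 5 lower (camera adjusted p = 0.444), with the alkaline phosphatase gene ALPI up by 1.58 ± 0.089 and the peptidase gene DPP4 down by 0.51 ± 0.03. The ATF4 response had 9 higher and 6 lower of 17 (12 and 4 with scaling to totals only, where the median of 0.12 was 0.245; camera adjusted p = 0.0704) and the chaperones 3 higher and 9 lower of 15 (4 and 9 adjusted over the list alone, 6 and 8 with scaling to totals only; camera adjusted p = 0.0625), and both passed the threshold without SGA315 replicate 3 (camera adjusted p = 0.0407 and 0.0422; 2.12e-05 to 0.367 and 8.12e-07 to 0.157 over the alternatives). Inflammation had 3 higher and 2 lower of 9 (3 and 1 adjusted over the list alone; camera adjusted p = 0.479), and BIRC3, an NF-kappaB target, rose by 1.46 ± 0.116. The medians of inflammation (−0.12) and of PPAR alpha and fatty acid oxidation (−0.05; 4 higher and 5 lower of 11, camera adjusted p = 0.818) were 0 and 0.07 with scaling to totals only (4 higher and 1 lower, and 5 higher and 3 lower), and the mean of the latter was 0.03. For lipoproteins (5 higher and 3 lower of 10, camera adjusted p = 0.76) and bile acid genes (0 higher and 1 lower of 3, and 1 and 1 with scaling to totals only; camera adjusted p = 0.975) the median and mean lay above 0 while camera's direction was down, and for inflammation the median and mean lay below 0 while camera's direction was up. Counts were 2 higher and 2 lower of 7 for p53 targets (camera adjusted p = 0.76; 4 and 1 with scaling to totals only), 0 and 2 of 3 for goblet cell markers (adjusted p = 0.199) and 1 and 2 of 3 for mesenchymal markers (adjusted p = 0.417), and CHGB rose by 0.30 ± 0.095. Where not given, counts adjusted over the list alone were the same.

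With SGA315, 5287 genes were higher and 4875 lower of 14683; the median size of the change among called genes was 0.42 on the log2 scale, and 703 rose and 317 fell at least 2-fold. The CPM of the groups did not overlap for 70.3% of genes (10% by chance). With scaling to totals only the calls were 6932 higher and 3619 lower (65.7% higher, against 52% with TMM), and 826 and 753 genes passed a test against a 1.5-fold change.

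The direct comparison of SGA360 with SGA315 asked where the ligands differed at the same dose and time. CYP1A1 was 192-fold lower with SGA360 than with SGA315 (−7.58 ± 0.05, adjusted p = 4.19e-80) and CYP1B1 9.19-fold lower (−3.20 ± 0.146). Of the cholesterol synthesis genes, most of which were lower with each ligand than with lovastatin alone, 19 of 20 were higher with SGA360 than with SGA315, at a median difference of 0.41. Metallothioneins were also higher with SGA360, with MT2A 4.4-fold higher (36.1 ± 4.23 against 8.07 ± 1.26 CPM, n = 3 each). Of 12 brush border genes 8 were lower and 2 higher with SGA360 (camera adjusted p = 9.01e-05; adjusted p = 0.0566 with an estimated correlation). FABP1, which encodes a fatty acid binding protein, was lower, at 23.9 ± 2.49 against 56.9 ± 3.26 CPM.

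Of the 8 AHR battery genes 7 were lower and 0 higher with SGA360 than with SGA315, also adjusted over the list alone (median −0.6, camera adjusted p = 1.53e-11; adjusted p = 0.0198 with an estimated correlation). ALDH3A1 differed by −1.93 ± 0.146, UGT1A6 by −0.73 ± 0.033 and TIPARP by −0.42 ± 0.053. AHRR did not pass the test, with a difference of −0.05 and a 95% interval of −0.27 to 0.16, and AHR was higher with SGA360 by 0.46 ± 0.045. The PXR and drug metabolism list had 7 lower of 8 (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 2.62e-05; adjusted p = 0.0375 with an estimated correlation).

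The 20 cholesterol synthesis genes had 19 higher and 0 lower with SGA360 (camera adjusted p = 3.35e-18; adjusted p = 0.00597 with an estimated correlation), the 12 fatty acid synthesis genes 11 and 0 (camera adjusted p = 1.41e-10; adjusted p = 0.0344 with an estimated correlation), and the 12 uptake and SREBP control genes 9 and 1 (camera adjusted p = 1.21e-06; adjusted p = 0.0347 with an estimated correlation), with the same counts adjusted over each list alone. INSIG1 differed by 0.54 ± 0.037, HMGCS1 by 0.41 ± 0.028 and NPC1L1 by 0.20 ± 0.046. For ABCA1 the difference was −0.03, with a 95% interval of −0.16 to 0.1. YAP targets had 6 higher and 1 lower of 8, also adjusted over the list alone (median 0.54, camera adjusted p = 7.42e-06; adjusted p = 0.0347 with an estimated correlation), with ANKRD1 higher by 0.95 ± 0.048 and AMOTL2, a gene of the angiomotin family, by 1.09 ± 0.037. All 5 tested metallothioneins were higher, also adjusted over the list alone (camera adjusted p = 1.21e-06; adjusted p = 0.0347 with an estimated correlation).

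Of 14 S phase genes 12 were higher and 0 lower with SGA360, also adjusted over the list alone (median 0.27, camera adjusted p = 4.92e-07; adjusted p = 0.0858 with an estimated correlation). For G2 and M phase genes 5 were higher and 1 lower of 12 (camera adjusted p = 0.286), and the median of 0.005 was −0.002 with scaling to totals only; MKI67 differed by −0.01 with a 95% interval of −0.07 to 0.06. Of 12 brush border genes 2 were higher and 8 lower, and 2 and 9 adjusted over the list alone (1 and 8 with scaling to totals only; median −0.6, camera adjusted p = 9.01e-05; adjusted p = 0.0566 with an estimated correlation), with ANPEP, an aminopeptidase, at −1.17 ± 0.072. PPAR alpha and fatty acid oxidation had 7 lower of 11 (camera adjusted p = 0.000496; adjusted p = 0.0757 with an estimated correlation), with CREB3L3, a transcription factor of lipid metabolism, at −1.68 ± 0.138. CPT1A did not pass the test, with a difference of −0.07 and a 95% interval of −0.25 to 0.11. Hypoxia and glycolysis had 8 higher and 3 lower of 15 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0196; adjusted p = 0.219 with an estimated correlation), and of 3 mesenchymal markers 1 was higher and 2 lower (camera adjusted p = 0.0266; adjusted p = 0.219 with an estimated correlation).

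The remaining lists had no camera call between the ligands. The NRF2 response had 4 higher and 6 lower of 16 (camera adjusted p = 0.927), with a median of 0 that was −0.01 with scaling to totals only, a mean of 0.02 and a camera direction of down. For the crypt and stem cell markers (2 and 2 of 7, camera adjusted p = 0.818) the median was 0.04 and the mean −0.08, and for LXR targets (1 and 1 of 5, camera adjusted p = 0.643) −0.03 and 0.03. SOX9, a crypt transcription factor, was lower with SGA360 by −0.77 ± 0.037, while RNF43, a Wnt feedback ligase, differed by 0.04 with a 95% interval of −0.05 to 0.13. Counts were 9 and 6 of 17 for the ATF4 response (10 and 6 adjusted over the list alone; camera adjusted p = 0.818), 6 and 2 of 15 for chaperones (7 and 4 adjusted over the list alone, 6 and 4 with scaling to totals only; camera adjusted p = 0.777), 4 and 4 of 9 for inflammation (camera adjusted p = 0.818), and 3 and 4 of 10 for lipoproteins (3 and 5 adjusted over the list alone; camera adjusted p = 0.242). They were 2 and 2 of 7 for p53 targets (camera adjusted p = 0.777), 2 and 0 of 3 for goblet cell markers (camera adjusted p = 0.12), and 1 and 0 of 3 for bile acid genes (1 and 2 adjusted over the list alone; camera adjusted p = 0.881). In the last list SLC51B, which overlaps RASL12, was higher by 0.40 ± 0.121, a call that ended without SGA360 replicate 2 (adjusted p = 0.0551; 0.00346 to 0.0551 over the alternatives). CHGB differed by −0.02, with a 95% interval of −0.2 to 0.16. Where not given, counts adjusted over the list alone were the same. Among called genes of at least 5 CPM without overlap between the groups, the keratin gene KRT4 (4.06-fold), ID1 (2.92-fold) and CHI3L1 (2.77-fold) were among the 8 largest differences towards SGA360, and LINC00673 (5.03-fold), CUBN, the endocytic receptor cubilin (4.61-fold), and the Ras exchange factor gene SOS1 (2.99-fold) among the 8 largest towards SGA315.

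Between the ligands 3201 genes were higher and 3065 lower with SGA360 of 14683; and 67 were higher and 139 lower at least 2-fold. The CPM of the groups did not overlap for 49.2% of genes (10% by chance), and 75 and 108 genes passed a test against a 1.5-fold change.

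The last comparison asked how far the responses to the ligands shared genes. 3682 genes were higher with both ligands and 3794 lower with both, and 5353 and 2550 with scaling to totals only. Lists of these sizes drawn independently would share 1658 and 1529, and simulated groups without change against the shared lovastatin libraries shared 0 and 0 by the edgeR test. At an unadjusted p under 0.05 the ligands shared 3902 higher and 3930 lower genes, and the simulated groups 69 and 63.6 on average. Because no gene changes in the simulated groups, a count near 0 after adjustment was fixed beforehand. These groups cannot say how much overlap to expect between ligands that each change many genes. 282 genes were called in opposite directions, 141 each way, against 1529 and 1658 for independent lists. CYP1A1, CYP1B1, LINC00673, CUBN and SOS1 were lower with SGA360 and higher with SGA315, and KRT4, CHI3L1, the growth factor gene TGFB2 and the G protein subunit gene GNG2 the reverse. Across 14683 genes the log2 fold changes correlated with r = 0.803 and a Spearman correlation of 0.815, where genes are not independent replicates, against a mean r of 0.49 in 20 simulations without change. Their covariance was 0.2082 against 0.00862 simulated, a difference of 0.1995, and 82.8% of genes had the same sign against 66.3% simulated. Part of the excess over independent lists may come from the 3 shared controls, which are too few to split. The simulations held only the spread between libraries of a group. A difference common to the 3 lovastatin libraries, as of a shared culture, was left out of them. The simulated covariance and counts of shared genes may therefore be too low. Of 7476 genes called by both in 1 direction, the direct test found SGA315 further from 0 for 2631 and SGA360 further for 710, and made no call for 4135. It also called 869 of 1451 genes called with SGA360 alone and 1476 of 2404 called with SGA315 alone.

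**Figure D4:**
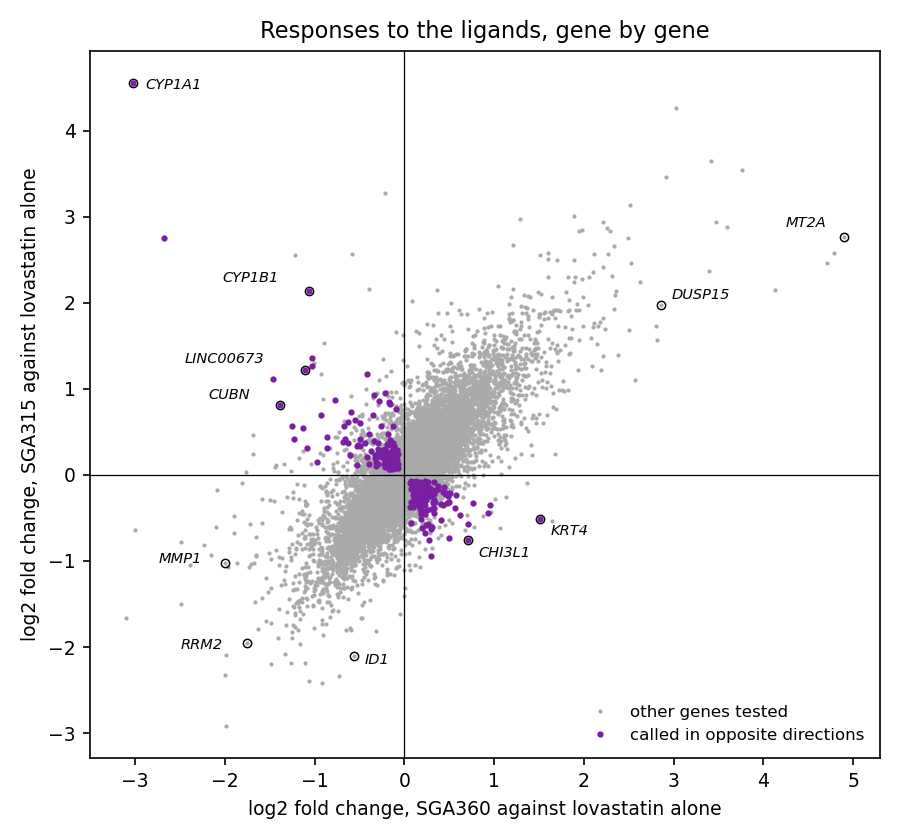
Log2 fold change against lovastatin alone of 14683 genes with SGA360 (horizontal axis) and SGA315 (vertical axis); purple points are the 282 genes called in opposite directions and circles mark named genes. Most genes lie along the rising diagonal (r = 0.803), and CYP1A1 stands apart at −3.03 and 4.56.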

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

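The tests of library correlations, of the list medians under another scaling, and of the noise between replicates were chosen only after the results they bear on were seen; the other tests in this part had their bounds set beforehand. 19 named genes were called in opposite directions by the ligands, and the direct test of SGA360 against SGA315 called each. Log2 differences below 0 were −7.58 for CYP1A1, −3.2 for CYP1B1, −2.33 for LINC00673, −2.2 for CUBN, −1.68 for CREB3L3, −1.58 for SOS1, −1.26 for FABP1, −1.17 for ANPEP and −0.45 for DGAT1, which overlaps HSF1 and is uncertain. Differences above 0 were 0.43 for ACSL3, 0.52 for AJUBA, 0.64 for RND3, 1.09 for AMOTL2, 1.23 for GNG2, 1.25 for CPA6, 1.28 for CXCL3, 1.3 for TGFB2, 1.47 for CHI3L1 and 2.02 for KRT4. Among 165 tested transcript entries without a gene name, which no comparison used, 50 were higher and 35 lower with SGA360 than with lovastatin alone, and 73 and 33 with SGA315. At least 2-fold, 13 were higher and 3 lower with SGA360, and 23 and 2 with SGA315.

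282 genes were called in opposite directions by SGA360 and SGA315. A single mislabelled library was argued against: 0 of the 9 libraries correlated best with a library of another group. Labels exchanged between whole groups would leave this result unchanged, so the test cannot decide about such an exchange. Of these genes 84.8% kept opposite signs both with scaling to totals only and with RLE, but this share decides nothing about scaling, since another scaling moves nearly all genes alike and turns those nearest 0. The 46 genes changed at least 1.25-fold both ways all kept theirs, so their signs do not rest on the choice among these scalings. Their size fixed this beforehand, because these scalings shift genes by less. Scaling in general therefore stays open for all 282 genes. Shared reads also stay open: 23.8% of them overlap another tested gene in the RefSeq annotation of GRCh38.p14, against 34.4% of 2000 random tested genes. A difference between the ligands may account for the rest, as a hypothesis that no other data here test.

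The cholesterol synthesis and S phase lists fell with both ligands. After a trend on GC content and gene length was removed, at least 98.1% of each list median was left, which argues against such a bias as the whole cause; 93.5% of tested genes had both values. With scaling to totals only, the list median nearest 0 was −0.461, against −0.576 with TMM. The falls therefore did not rest on the choice between these scalings. That choice moves nearly all genes alike and by little, so it cannot decide about scaling in general. An effect of the ligands stays open, as a hypothesis, since it was found and tested on the same libraries. A difference between the cultures of the groups was not tested for these lists and also stays open. Both falls were measured against the same lovastatin libraries, so they are not independent observations.

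More than 60% of genes passed the test against lovastatin alone with each ligand. If the 3 libraries of a group came from 1 culture or RNA pool, small differences between cultures could pass the test. The counts of replicate pairs differed by more than counting noise, with a group mean of chi-square per degree of freedom of up to 1.852. That is over the bound of 1.5 set for separate cultures, but that bound was wrong, because library preparation alone also adds noise. Shared cultures therefore cannot be told apart from the groups, and a broad effect of each ligand also stays open.

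The 6 libraries of each comparison allow 10 splits, too few for a share under 0.05. By edgeR the real split called 9209 genes for SGA360, 10162 for SGA315 and 6266 for SGA360 against SGA315, and 1 of the 10 splits, the real one, called as many. The highest of the other splits called 0 genes in each. At an unadjusted edgeR p under 0.05 their highest counts were 216, 188 and 650 genes, against 9642, 10479 and 7243 for the real splits. Every other split mixes libraries of both real groups, so the real difference enters its spread and lowers its calls. These counts are therefore not those of groups without change, and the contrast with the real splits decides nothing. DESeq2 was not run on the splits.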

How the results depend on the processing

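The test against a 1.5-fold change and scaling to totals only were chosen after the data were seen; the other settings below were fixed before. Against a 1.5-fold change, 429 genes were higher and 407 lower with SGA360, 826 and 753 with SGA315, and 75 and 108 in SGA360 against SGA315. It left 298 genes higher with both ligands, 291 lower with both, 1 higher with SGA360 and lower with SGA315, and 4 the reverse. DESeq2 gave 88 genes lower with SGA360 and higher with SGA315. Without a filter on low counts the correlation of the fold changes was 0.606. With scaling to totals only, the log2 fold changes with SGA360 were 0.089 for TIPARP, 0.055 for FGF19, 0.108 for TFF3, 0.079 for FKBP5 and 0.096 for TNFRSF19, and that of TFF3 with SGA315 was 0.016, all of the other sign. With an estimated correlation 6, 4 and 7 lists passed in the 3 comparisons (12, 10 and 12 with the preset), and with fry 22, 23 and 17. Fry gave adjusted p = 0.0385 and 0.000623 for LXR targets with SGA360 and SGA315 and 0.596 for the NRF2 response between the ligands, each in the other direction, and bile acid handling with SGA315 had 0.991 with RLE, also reversed. Except where a setting only raises the fold tested, the cause was not tested. Correlations of deviations between libraries of the same replicate number were small (−0.024 to 0.046). Still, 6 of 9 libraries correlated best with their own number, so a weak pairing stays open. With a replicate block no call of the 369 gene results or of the lists changed. The block gave 4681 and 4660 genes with SGA360, 5347 and 4927 with SGA315, and 3287 and 3156 between the ligands. Each count was slightly above that of the main fit. TFF3 with SGA360 became 0.005 with the block. Leaving out each library gave 4054 to 4709 and 4355 to 4765 genes with SGA360, 4770 to 5139 and 4693 to 5068 with SGA315, and 2760 to 3183 and 2575 to 3051 between them. It gave 3205 to 3648 genes higher with both, 3594 to 3872 lower with both, 105 to 143 and 113 to 151 opposite, a correlation of 0.78 to 0.809, and 12 to 12, 10 to 12 and 12 to 12 lists. Log2 fold changes that crossed 0 were −0.018 to 0.087 for NPC1L1, −0.262 to 0.121 for FGF19 and −0.096 to 0.083 for TFF3 with SGA360, and between the ligands −0.151 to 0.043 for AHRR, −0.072 to 0.021 for ABCA1, −0.056 to 0.017 for CHGB and −0.008 to 0.078 for NKD1. List adjusted p ranges were 0.887 to 0.985 and 0.92 to 0.993 for LXR targets, 0.805 to 0.976 and 0.91 to 0.998 for bile acid handling with SGA360 and SGA315, and 0.766 to 0.986 for the NRF2 response between them. Of 369 gene results, 8 lost their call without 1 library, 5 with DESeq2, 5 with scaling to totals only and 1 without the filter, while 3 gained a call without 1 library, 4 with scaling to totals only and 1 with RLE. Depth limits genes near 0.178 to 0.243 CPM, the level of 3 counts.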

Other observations

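The lists and genes of this part, and its tests, were chosen after the results of single genes were seen, with bounds set before each list was tested. Camera p-values of the lists added in this part were adjusted over these lists alone, apart from the 72 tests. That adjustment does not cover the choice of the lists. Further genes moved in opposite directions. FGFR2, a growth factor receptor gene, rose from 254 ± 5.09 to 341 ± 4.04 CPM with SGA360 and fell to 198 ± 6.37 CPM with SGA315 (n = 3 each). RHOD also rose with SGA360 and fell with SGA315, with a difference between the ligands of 0.93 ± 0.107. The reverse held for BMF, a pro-apoptotic gene (difference −1.25 ± 0.036), AKR1C2, an aldo-keto reductase gene (−1.09 ± 0.049), DEPTOR, an inhibitor of mTOR (−1.07 ± 0.093), and GDPD5 (−0.99 ± 0.062). AKR1C2 has close paralogs, so its counts are uncertain. Among mesenchymal markers, VIM rose from 167 ± 4.25 to 221 ± 6.78 CPM with SGA360 and to 294 ± 6.59 CPM with SGA315, while FN1 fell by 0.76 ± 0.028 and 0.42 ± 0.028 on the log2 scale.

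Metallothioneins rose with both ligands, more with SGA360 (for the list with SGA315, adjusted p = 0.157 with an estimated correlation). A zinc-type response is one hypothesis: SLC30A1, a zinc exporter gene induced by zinc, rose by 0.53 with SGA360 and 0.23 with SGA315, and was higher with SGA360 by 0.30 in the direct test, as this hypothesis needs. The zinc importer gene SLC39A10 fell by 0.34 and 0.40. A glucocorticoid-type response may also raise metallothioneins. Its 7 tested target genes had a median of −0.04 with SGA360, under the bound of 0.1 set against it, but 2 were higher and 2 lower, with SGK1 at −1.04 and KLF9 at 0.71, so it stays open. With scaling to totals only the median was 0.08, with 3 higher and 1 lower. The call of KLF9 ended without SGA360 replicate 2 (adjusted p = 0.145) and with DESeq2 (adjusted p = 0.0528; 0.00168 to 0.145 over the alternatives). The value of FKBP5 with SGA360 was −0.04, and 0.08 with scaling to totals only.

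ID1 fell with SGA315, and lower expression of BMP-SMAD targets could be part of that. The 6 other BMP targets tested had a median of −0.36 with SGA315, between the bounds of −0.5 and −0.2 (also with scaling to totals only, −0.24), with 1 higher and 3 lower (camera adjusted p = 0.337), so this stays open. SMAD6 fell by 0.74, BAMBI by 0.38 and ID2 by 0.33. SMAD9 rose by 0.23 (adjusted p = 0.029). That call ended without lovastatin replicate 2 (adjusted p = 0.0516), without lovastatin replicate 3 (0.151) and without SGA315 replicate 1 (0.178). It also ended with DESeq2 (0.15) and without the filter on low counts (0.0594), with 0.000955 to 0.178 over the alternatives. The falls were not particular to SGA315. With SGA360 the same 6 targets had a median of −0.14, with 0 higher and 3 lower (camera adjusted p = 0.393). SMAD6 fell by 0.66, SMAD9 by 0.61 and ID2 by 0.27 with SGA360. With scaling to totals only that median was −0.02, with 1 higher and 3 lower. No bounds were set for SGA360.

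FOSL1 and EGR1 fell with both ligands. Lower expression of ERK targets is a hypothesis tested on 10 other targets: the median was −0.78 with SGA360, the ligand nearer 0, and −1.01 with SGA315, under the bound of −0.3, and −0.67 and −0.88 with scaling to totals only. With SGA360 0 were higher and 9 lower, and with SGA315 0 and 10 (camera adjusted p = 1.94e-06 and 1.53e-07; adjusted p = 0.101 with an estimated correlation in both). DUSP6 fell by 1.52 and 1.36, SPRY4 by 1.10 and 1.34, ETV4 by 1.00 and 0.76, ETV5 by 1.04 and 1.24, and EPHA2 by 0.92 and 1.68. CCND1 and PHLDA1 also fell with both, while DUSP4 lay above 0 with SGA360, at 0.19, and was not called (adjusted p = 0.155). It was called higher without lovastatin replicate 2 (0.31, adjusted p = 0.0391) and with scaling to totals only (0.305, adjusted p = 0.0206; 0.0206 to 0.672 over the alternatives). SPRY4 was higher with SGA360 than with SGA315 by 0.24, which ended without SGA360 replicate 2 (adjusted p = 0.297), without SGA315 replicate 1 (0.16) and with DESeq2 (0.0529), with 0.00384 to 0.297 over the alternatives. SPRY1, of the same gene family as SPRY4 but outside the list, was called higher with SGA360 (0.33, adjusted p = 0.00232). It was called lower with SGA315 (−0.44). The count of 0 higher with SGA360 therefore depends on the genes chosen for the list. The calls of SPRY1 were not followed over the alternatives. No measure of ERK activity was analysed here.

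LGR5, AXIN2 and RNF43 fell with both ligands, and lower expression of Wnt targets is a hypothesis tested on 8 further targets. Their median was −0.33 with SGA360, the ligand nearer 0, and −0.55 with SGA315, under the bound of −0.3, but −0.22 with SGA360 with scaling to totals only (−0.43 with SGA315), between the bounds, so this stays open. With SGA360 0 were higher and 5 lower (1 and 5 with scaling to totals only), and with SGA315 0 and 7 (camera adjusted p = 0.0193 and 0.00332; adjusted p = 0.159 and 0.101 with an estimated correlation). NKD1 fell by 1.12 and 1.15, LEF1 by 0.67 and 1.16, SP5 by 0.85 and 0.35, TCF7 by 0.37 and 0.64, and ZNRF3 by 0.29 and 0.66. TNFRSF19 was −0.02 with SGA360, and 0.10 and called with scaling to totals only (adjusted p = 0.0132; 0.0132 to 0.722 over the alternatives). NKD1 did not pass the test between the ligands (0.03, 95% interval −0.1 to 0.16).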
